A study of Mus musculus with 2 samples.

How the data were processed

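The series held H3K27ac ChIP-seq of hindbrain from newborn mice (postnatal day 0), with 2 biological replicates of mixed sex in 1 group, each from pooled animals and from fragments of 300 to 500 bp per the labels. Both replicates were used, and the group and replicate numbers were taken from the labels. Whether the pools came from separate litters was not given in the sources used here. The authors deposited 4 peak lists in narrowPeak format on the mm10 assembly, per the labels and the descriptions deposited with the files. A list was called on each replicate's alignments against control alignments, another on both replicates together (the pooled list), and the replicated list is a subset of the pooled list that the authors derived from it and from both single lists. The overlap rule behind the replicated list, the aligner, the peak caller and their versions were not given in the sources used here.

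Per the deposited format, each peak carries a display score from the authors, a fold enrichment (a ratio of ChIP over control), a −log10 p and a −log10 q, and the position of its summit. The score was not used. The fold and −log10 values were taken from the authors as deposited and served to describe, rank or filter peaks. Fold values of the replicates come from separate calls and were not put on a common scale, so the mean and SD over replicates (n = 2) include any difference in scale between the calls. The files hold no read counts, so the depth of each library is unknown and no count test was possible. The lowest −log10 p in the lists was 2.00 to 2.04. In the single-replicate lists, 88.6% and 95.8% of peaks had a q below 0.05, and in the replicated list 99.8% did.

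Peaks on the assembled chromosomes were used, and the 8 replicated peaks on unplaced or unlocalised scaffolds were left out. Gene annotation was GENCODE M21 on GRCm38, the build that mm10 denotes, with 21853 protein-coding genes and 54361 TSSs of protein-coding transcripts. A promoter peak overlapped the 1000 bp either side of any TSS of a gene, and a distal peak overlapped no such window and was assigned to the nearest TSS. Coordinates are counted from 1. Non-coding genes were taken from the same annotation for the named regions, a step added after the data were examined. Intervals for shares are Wilson intervals at 95% and cover counting error over peaks or genes only.

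Replicates were compared by the share of peaks covered over at least 50% of their length by the other list, beside 100 seeded shuffles within chromosomes, and by Spearman's rho across replicated peaks. Before the data were examined, 36 gene lists and 20 motifs were fixed. The lists were hindbrain, forebrain and midbrain regulators, Hox paralogs 1 to 4, 5 to 8 and 9 to 13, housekeeping, neuronal activity and cell cycle genes, the Hedgehog and Notch pathways, markers of cell types of the hindbrain and markers of outside tissues. Of 543 distinct genes on the lists, 542 matched the annotation, and the erythroid gene Ahsp did not. Some genes stand in several lists, such as 25 of the 34 hindbrain regulators. Each list's promoter share was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists at 0.05. Distal peaks per gene were compared with 10000 random lists matched by decile on the length of each gene's nearest-TSS territory. Motifs were searched on both strands in 500 bp windows at the summits of distal peaks, with an equal number of windows outside all peaks matched in bins of 1% GC (49.7% GC in each set), and compared by Fisher's exact test. These p-values describe the lists of genes or windows in these peak sets, not variation between animals.

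The rule for named genes, fixed before the data were examined, took the 10 genes with most distal peaks, the genes nearest to the 10 widest regions (peaks within 1 kb merged), the genes nearest to the 10 distal peaks of highest fold, up to 3 members of highest and 3 of lowest promoter fold in lists described, every member against the majority of its list where these were 5 or fewer, and every Hox gene. Alternatives were the list of either replicate alone, the pooled list, peaks with −log10 q of 5 or more, promoter windows of 500 bp and 2.5 kb, the most 5' TSS of each gene, overlaps of 1 bp and 80%, lists of equal length, a limit of 100 kb for distal peaks, motif windows of 300 bp, windows not matched on GC, random lists matched on CpG ratio and genes with a CpG ratio of 0.6 or more. Limiting the replicated list to its 40092 peaks that share at least 1 bp with each replicate was added after the data were examined.

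The steps were tested on simulated data. A planted overlap of 40.5% was recovered as 40.5% over 20000 peaks. Lists with a promoter share set far above or far below that of other genes were called in 87.5% of cases and unchanged ones in 0.385%, over 21853 genes. Smaller changes were not simulated, so a list that did not pass the promoter test may still differ. Lists given 4 times the distal peaks were called in 53.3% of cases and unchanged ones in 0%, so a list that missed the distal threshold may still differ. With a motif planted in part of 10000 windows, matches were expected in 5.39% of windows, background matches included, and were found in 5.45%. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9.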

Results

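Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and active distal elements, was mapped by chromatin immunoprecipitation sequencing in hindbrain of newborn mice. The hindbrain gives rise to the cerebellum, pons and medulla. The study held 1 group with 2 biological replicates, each a pool of male and female mice on postnatal day 0, and replicate 1 came from 15 mice. No other tissue or stage was compared, so the comparisons below are between the replicates, between classes of genes and between genomic places. The deposited lists held 70789 peaks for replicate 1, 96871 for replicate 2, 107164 for both replicates called together (the pooled list) and 51093 in the authors' replicated list. These lists covered 34.1, 59.2, 68.4 and 52.7 Mb of the mm10 genome, respectively. Read depth is unknown, because the files hold peaks and no counts. All fold enrichments are the authors' own values of ChIP over control at a peak.

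Strong H3K27ac peaks were shared by both pools of mice, and weak ones often were not. Of the 70780 replicate 1 peaks on the assembled chromosomes, 50170 (70.9%) had at least 50% of their length covered by replicate 2 peaks, against 2.30% when peaks were placed at random on the same chromosomes (mean of 100 shuffles). Of the 96860 replicate 2 peaks, 29279 (30.2%) were found in replicate 1, against 1.22% at random. In the quartile of peaks with the highest fold enrichment the shares were 99.1% and 76.9%, and in the lowest quartile they were 48.1% and 9.07%. Peaks that were found again lay at promoters more often than those that were not, at 35.5% against 7.88% for replicate 1 and 42.6% against 10.5% for replicate 2. Across the 26458 replicated peaks covered over at least 50% of their length in each replicate, Spearman's rho of fold enrichment was 0.864 and Pearson's r of its log2 was 0.896. This correlation is across peaks, which are not independent replicates. The share for replicate 2 rested on the overlap asked for, at 44.7% with 1 bp and 12.1% with 80% of the peak. The replicated list was not limited to peaks called in each pool: 10278 of its 51085 peaks on assembled chromosomes (20.1%) had no replicate 1 peak, and 829 had no replicate 2 peak.

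**Figure D1:**
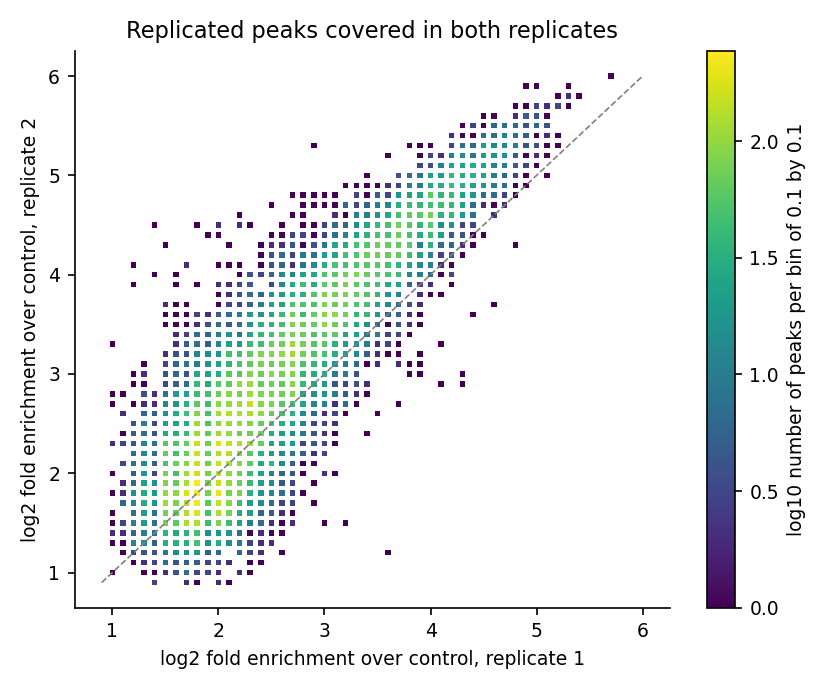
Log2 fold enrichment of ChIP over control in replicate 1 (x axis) and replicate 2 (y axis) for the 26458 replicated peaks covered over at least 50% of their length in each replicate; squares are coloured by the log10 number of peaks and the dashed line marks equal values. Strong peaks were strong in both (rho = 0.864).

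H3K27ac peaks were concentrated at gene promoters and depleted between genes. Of the replicated peaks, 15157 (29.7%, 95% Wilson interval 29.3 to 30.1) lay within 1 kb of the transcription start site (TSS) of a protein-coding gene, 7.62 times the 3.89% of shuffled peaks. Introns held 41.2% of peaks (36.5% shuffled) and intergenic sequence 25.8% (57.2% shuffled), while coding exons held 1.74% and untranslated exons 1.59%. Promoter peaks were stronger and wider than distal peaks, with a median fold enrichment of 9.29 against 3.88 and a median width of 1248 bp against 634 bp. A promoter peak was present at 12578 of 21853 protein-coding genes (57.6%), and the lists of the single replicates gave 58.6% ± 2.95 (SD, n = 2). The share was 91.8% among the 8227 genes whose promoter had a CpG observed/expected ratio of 0.6 or more and 36.9% among the other 13626. Single lists gave lower promoter shares of peaks, 23.8% ± 5.16 (SD, n = 2), with the longer replicate 2 list at 20.2%.

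Genes that pattern the hindbrain carried promoter H3K27ac far more often than genes that pattern the forebrain. A promoter peak was found at 30 of 34 hindbrain regulators (88.2%) and at 6 of 34 forebrain regulators (17.6%), a difference of 70.6 percentage points (two-sided Fisher's exact test, p = 5.06e-09). The difference was 58.8 points in the list of replicate 1 and 67.6 points in that of replicate 2. Some genes on these lists are neighbours in shared acetylated regions, such as Hoxb2, Hoxb3 and Hoxb4 or Zic1 and Zic4. They are not independent, so p-values of this comparison describe gene counts only. The strongest hindbrain promoters were those of Meis1, a homeodomain cofactor of Hox proteins, at 26.2 ± 7.93-fold (SD, n = 2), and of the zinc finger genes Zic4 and Zic1, which act in cerebellar granule cells, at 23.2 ± 6.47 and 18.1 ± 5.73-fold (SD, n = 2). The weakest with a fold in each replicate were Phox2b, a regulator of visceral motor and autonomic neurons, at 3.62 ± 0.646-fold, Pax8 at 4.10 ± 0.329-fold and Atoh1, the proneural gene of the rhombic lip, at 4.11 ± 1.39-fold (SD, n = 2). Hoxb1, Pax5, Ptf1a and Phox2a had no promoter peak in any of the deposited lists.

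The forebrain regulators without a replicated promoter peak included Foxg1, Emx1, Emx2, Six3, Tbr1 and all 4 Dlx genes on the list, factors of the telencephalon, and Nkx2-1 and Rax of the hypothalamus. The 6 with a peak were Ebf1 at 10.6 ± 6.31-fold, Satb2 at 7.34 ± 2.05, Neurod6 at 7.14 ± 0.6505, Bcl11b at 7.03 ± 0.503, Eomes at 4.30 ± 1.12 and Lhx2 at 3.10 ± 0.476-fold (SD, n = 2). Several of these have known roles outside the forebrain as well, Eomes in cerebellar unipolar brush cells among them. Among genes with a promoter CpG ratio of 0.6 or more, 24 of 26 hindbrain regulators (92.3%) and 4 of 24 forebrain regulators (16.7%) had a peak (Fisher's exact test, p = 5.75e-08). Random lists matched on CpG ratio carried peaks at 86.2% and 86.4% of genes, so the departure from genes of like promoters was on the forebrain side. Midbrain regulators had peaks at 5 of 14 (35.7%, adjusted exact p = 0.128): En2 at 10.9 ± 4.27-fold, En1 at 6.18 ± 2.78, Nr4a2 at 4.64 ± 2.09, Otx2 at 4.54 ± 1.12 and Lmx1a at 4.48 ± 0.869-fold (SD, n = 2). En1, En2 and Lmx1a are also on the hindbrain list, and the share of midbrain regulators was 57.1% in the list of replicate 2.

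The Hox genes, which set position along the body axis, split by paralog number. Promoter peaks were found at 10 of 12 genes of paralogs 1 to 4 and at none of the 16 genes of paralogs 9 to 13 (two-sided Fisher's exact test, p = 5.03e-06), with the same counts in each replicate. Paralogs 5 to 8 had peaks at 6 of 11 genes (54.5%), so that 16 of the 39 Hox genes were marked. In Hoxa, fold enrichment was 6.43 ± 2.37 at Hoxa1, 12.6 ± 2.98 at Hoxa2, 4.35 ± 0.689 at Hoxa3, 8.71 ± 1.38 at Hoxa4 and 6.35 ± 0.0307 at Hoxa5 (SD, n = 2). Hoxa6 had a peak in replicate 2 alone (3.31-fold), and Hoxa7, Hoxa9, Hoxa10, Hoxa11 and Hoxa13 had none. In Hoxb, values were 10.7 ± 3.98 at Hoxb2, 13.5 ± 4.30 at Hoxb3, 8.31 ± 2.30 at Hoxb4, 6.14 ± 1.88 at Hoxb5, 3.75 ± 0.826 at Hoxb6, 3.18 ± 0.470 at Hoxb7 and 3.44 ± 0.195 at Hoxb8 (SD, n = 2). Hoxb1, Hoxb9 and Hoxb13 had no promoter peak.

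In Hoxc, peaks were limited to Hoxc4 (6.27 ± 0.578-fold) and Hoxc5 (3.97 ± 1.31-fold, SD, n = 2), and Hoxc6, Hoxc8, Hoxc9, Hoxc10, Hoxc11, Hoxc12 and Hoxc13 had none. In Hoxd, they were limited to Hoxd3 (10.1 ± 0.430-fold) and Hoxd4 (5.15 ± 1.16-fold, SD, n = 2), and Hoxd1, Hoxd8, Hoxd9, Hoxd10, Hoxd11, Hoxd12 and Hoxd13 had none. Neighbours within a cluster share chromatin and are not independent, so the p-value describes these gene counts only. Several Hox genes have long annotated upstream transcripts, and with only the most 5' TSS of each gene the difference was 50 percentage points (Fisher's exact test, p = 0.00245). Against all other genes, neither paralogs 1 to 4 (83.3%, adjusted exact p = 0.104) nor paralogs 5 to 8 (adjusted exact p = 1) differed, whereas paralogs 9 to 13 were lower (0%, adjusted exact p = 1.98e-05).

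**Figure D2:**
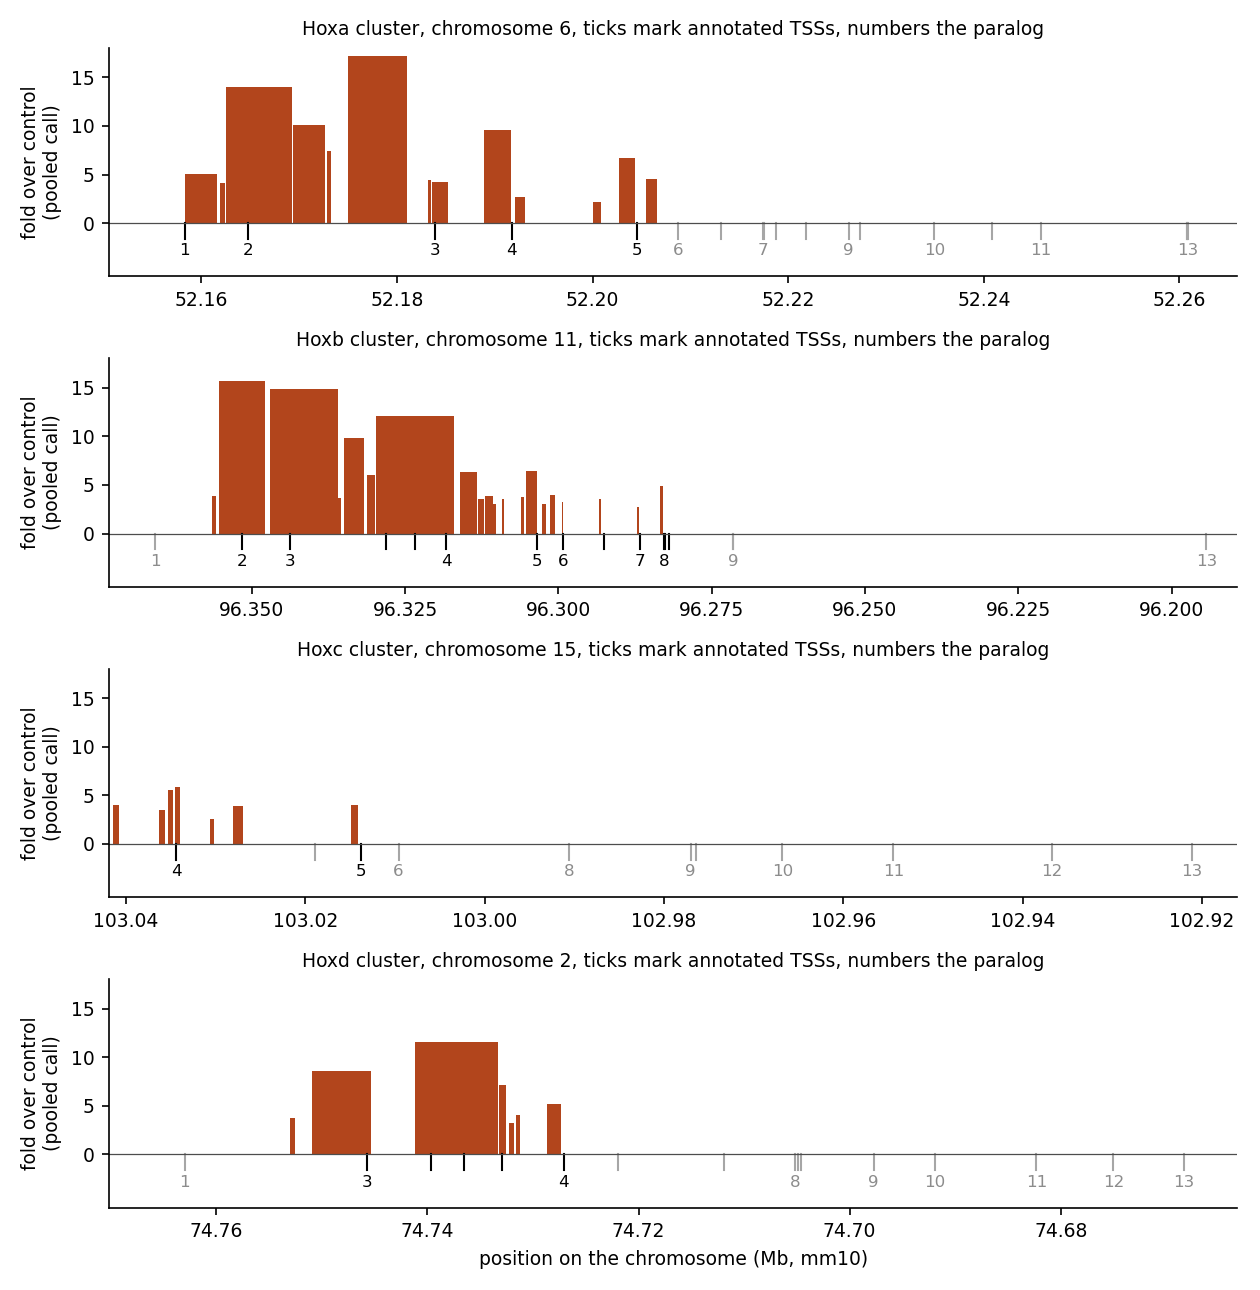
Replicated H3K27ac peaks in the Hoxa, Hoxb, Hoxc and Hoxd clusters along their chromosomes (x axis, Mb, mm10), each bar spanning a peak with its fold enrichment in the pooled call as height (y axis). Ticks mark annotated TSSs and numbers the paralog, in black where a peak lay within 1 kb and in grey where none did; no promoter of paralogs 9 to 13 had a peak.

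The genes of the pan-neuronal and progenitor lists were marked throughout. Promoter peaks were found at 20 of 20 pan-neuronal genes and 20 of 20 genes of neural progenitors and radial glia (each 100%, adjusted exact p = 0.000151, against 57.5% of other genes). Among pan-neuronal genes the highest were the intermediate filament gene Ina at 26.02 ± 4.99-fold, the neuronal repressor Myt1l at 23.1 ± 7.32 and Rtn1 at 22.0 ± 5.03, and the lowest Syn1 at 7.38 ± 3.98, the migration gene Dcx at 8.09 ± 1.53 and Syp at 9.56 ± 5.57 (SD, n = 2). The summit of the peak at Ina lay nearer to the TSS of Nt5c2. In progenitors the nuclear factor gene Nfib (23.5 ± 7.87-fold), the RNA-binding gene Msi1 (23.3 ± 6.48) and Nfix (18.1 ± 4.70) led, and Prom1 (3.62 ± 0.764), Nes (5.55 ± 0.887) and Sox21 (5.65 ± 0.0406) were lowest (SD, n = 2), while Sox3 had a fold in replicate 2 alone. Markers of the cerebellar granule lineage had peaks at 22 of 23 genes (95.7%, adjusted exact p = 0.000304), led by Meis1, Zic4 and Zic5 (20.4 ± 2.49-fold) and lowest at Atoh1, Nhlh1 (4.43 ± 1.30-fold) and Gli2 (5.33 ± 0.414-fold, SD, n = 2). The exception was Gabra6, a receptor subunit of mature granule cells.

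Genes of inhibitory neurons and of astrocytes were also marked more often than other genes. GABA and glycine neurons had peaks at 14 of 15 genes (93.3%, adjusted exact p = 0.00680), with the scaffold gene Gphn at 24.6 ± 5.94-fold, the glycine transporter Slc6a9 at 16.2 ± 5.01 and Slc6a1 at 13.1 ± 4.00, while Ptf1a, a determinant of these neurons, had none. Astrocyte genes had peaks at 16 of 17 (94.1%, adjusted exact p = 0.00410), from the glutamate transporter Slc1a2 (16.4 ± 6.75-fold), Glul (16.1 ± 5.53, its summit nearer to Teddm2) and Atp1a2 (13.2 ± 4.46) down to Gfap (5.37 ± 1.64), Aqp4 (5.21 ± 0.913) and S100b (4.73 ± 1.23, SD, n = 2). Ntsr2 was the astrocyte gene without a replicated peak. Shares that did not pass the test were those of Purkinje cells (14 of 18, 77.8%, adjusted exact p = 0.117), glutamatergic neurons (10 of 14, 71.4%, adjusted exact p = 0.444), oligodendrocyte precursors (12 of 14, 85.7%, adjusted exact p = 0.0696, without Neu4 and C1ql1) and noradrenergic neurons (6 of 12, 50%, adjusted exact p = 0.794). Purkinje promoters ranged from Rora, needed for Purkinje cell maturation (18.05 ± 3.66-fold), to Pcp4 (3.75 ± 0.829-fold, SD, n = 2), and Pcp2, Calb1, Skor2 and Itpr1 had no replicated peak. Among glutamatergic genes Slc17a6 was marked, and Slc17a7, Slc17a8, Tbr1 and Pou4f1 were not. Purkinje cell genes passed with the replicate 2 list alone (adjusted exact p = 0.0246) and with the pooled list (adjusted exact p = 0.000938). Oligodendrocyte precursors passed with the pooled list (adjusted exact p = 0.0215), with windows of 2.5 kb (0.0166) and with the most 5' TSS (0.0391).

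Markers of serotonergic and cranial motor neurons, myelinating oligodendrocytes, microglia, and meninges and fibroblasts were marked less often than other genes. Peaks were found at 2 of 12 serotonergic genes (16.7%, adjusted exact p = 0.00998), namely Nkx2-2 at 6.35 ± 1.43-fold and Lmx1b at 5.39 ± 0.664-fold, and at 2 of 14 cranial motor neuron genes (14.3%, adjusted exact p = 0.00408), namely Ret at 4.10 ± 0.170-fold and Phox2b (SD, n = 2). Myelinating oligodendrocytes had peaks at 4 of 14 genes (28.6%, adjusted exact p = 0.0450), with Mbp at 7.24 ± 1.29, Cnp at 6.202 ± 1.32, Aspa at 4.84 ± 2.87 and Ugt8a at 3.87 ± 1.01-fold (SD, n = 2). Microglia had peaks at 3 of 16 genes (18.8%, adjusted exact p = 0.00410), which were Sall1 at 7.89 ± 4.70-fold, Csf1r at 3.84 ± 0.954-fold (SD, n = 2) and Hexb, in replicate 2 alone at 4.35-fold. Genes of meninges and fibroblasts had peaks at 4 of 16 (25%, adjusted exact p = 0.0157), with Foxc1 at 5.80 ± 2.23, Pdgfra at 5.09 ± 0.733, Tbx18 at 3.67 ± 0.217 and Igf2 at 3.44 ± 0.894-fold (SD, n = 2). Endothelial cells and pericytes (8 of 18, 44.4%, adjusted exact p = 0.371) and choroid plexus and ependyma (6 of 16, 37.5%, adjusted exact p = 0.146) did not differ by the test. The ciliary regulator Foxj1 was highest of the latter at 11.4 ± 2.66-fold (SD, n = 2).

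These counts rose in the longer list of replicate 2. There, peaks were found at 50% of serotonergic genes (adjusted exact p = 0.668), 50% of microglial genes (adjusted exact p = 0.553) and 56.2% of genes of meninges and fibroblasts (adjusted exact p = 0.872), so that these lists no longer differed from other genes. Microglia did not differ with the pooled list either (adjusted exact p = 0.531). The call for myelinating oligodendrocytes was kept in 2 of 9 alternatives, windows of 2.5 kb and the most 5' TSS. It ended in the lists of replicate 2 and replicate 1 alone (adjusted exact p = 0.243 and 0.0737), in the pooled list (0.0770), with −log10 q of 5 or more (0.0773), with windows of 500 bp (0.0729), with only peaks found in each replicate (0.0771) and against CpG-matched lists. Endothelial cells and pericytes were lower with only peaks found in each replicate (adjusted exact p = 0.0411). With the pooled list, the share of meninges and fibroblasts lay above that of other genes by 7.49 percentage points (adjusted exact p = 0.653).

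Most genes of tissues outside the hindbrain had no promoter peak. No peak was found at the 16 genes of intestine and lung epithelium (0%, adjusted exact p = 1.98e-05), and 1 of 13 erythroid genes had a peak (7.69%, adjusted exact p = 0.000969), Tal1 at 6.11 ± 2.17-fold (SD, n = 2), with none at the globin genes. Skeletal muscle had 1 of 16 (6.25%, adjusted exact p = 0.000151), at Mylpf (10.1 ± 4.40-fold, SD, n = 2), where the summit lay nearer to the TSS of Tbc1d10b. Liver (2 of 16, 12.5%, adjusted exact p = 0.00124) was limited to Apoa1 and to Ttr, which choroid plexus also makes, each with a fold in replicate 2 alone. Germ cells (2 of 16, 12.5%, adjusted exact p = 0.00124) were limited to Zpbp (12.2 ± 4.78-fold) and Dazl (5.26 ± 1.87-fold), and cartilage and bone (2 of 14, 14.3%, adjusted exact p = 0.00408) to Sox9 (9.65 ± 2.14-fold), a glial gene as well, and Runx2 (3.29 ± 0.323-fold, SD, n = 2). Kidney (3 of 16, 18.8%, adjusted exact p = 0.00410) showed Pax2, also a hindbrain gene (4.96 ± 0.553-fold), Slc22a12 (3.67 ± 0.770-fold) and Lrp2 (3.43 ± 0.189-fold, SD, n = 2). Lymphocytes (3 of 16, 18.8%, adjusted exact p = 0.00410) showed Foxp3 (13.8 ± 5.04-fold), Rag1 (4.04 ± 0.309-fold, SD, n = 2) and Lck, in replicate 2 alone at 7.39-fold. The summit at Foxp3 lay nearer to Ppp1r3f. Heart (4 of 16, 25%, adjusted exact p = 0.0157) showed Myh7 (11.03 ± 1.69-fold), Ryr2 (9.02 ± 1.97-fold), Nppa (5.199 ± 1.10-fold, SD, n = 2) and Myl2, in replicate 2 alone at 5.06-fold. The call for heart ended with a promoter window of 2.5 kb (adjusted exact p = 0.154), and that for cartilage and bone in the list of replicate 2 (adjusted exact p = 0.139).

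Housekeeping genes and genes of signalling pathways completed the lists. All 24 housekeeping genes had peaks (100%, adjusted exact p = 2.12e-05), with Actb at 46.5 ± 13.8-fold, Ubb at 32.5 ± 10.6 and Ywhaz at 31.9 ± 8.10 the highest and Gusb at 4.29 ± 0.0882-fold the lowest (SD, n = 2). Neuronal activity genes were marked at 13 of 14 (92.9%, adjusted exact p = 0.00998), with Dusp1 at 23.1 ± 11.3-fold and Homer1 at 19.9 ± 9.29-fold (SD, n = 2) highest and Egr3 without a peak. The Hedgehog pathway, which drives granule cell precursor division, was marked at 13 of 14 genes (92.9%, adjusted exact p = 0.00998), led by Gas1 (17.5 ± 5.26-fold), the receptor Ptch1 (16.9 ± 2.95-fold) and Smo (15.3 ± 5.31-fold, SD, n = 2), with Hhip the exception. The Notch pathway was marked at 15 of 17 genes (88.2%, adjusted exact p = 0.0173), led by Maml1 (29.3 ± 5.80-fold) and the nuclear effector Rbpj (28.1 ± 3.48-fold, SD, n = 2), with Dll4 and Heyl the exceptions. Cell cycle genes, at 16 of 20 (80%, adjusted exact p = 0.0584), did not pass, with Mki67, Ccnb1, Bub1 and Mcm3 unmarked. They did in the list of replicate 2 alone (adjusted exact p = 0.00245), in the pooled list (0.00230) and with the most 5' TSS (0.0370).

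In all, 26 of the 36 lists differed from other genes (10 higher, 16 lower; two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists), and 27 did so before adjustment. These p-values compare genes within these peak lists and do not measure spread between animals. Against random lists matched on promoter CpG ratio, 14 lists differed and 13 of them were among the 26. Of the higher lists, 3 kept their call there (pan-neuronal genes, astrocytes and the cerebellar granule lineage) and 7 lost it. These were hindbrain regulators (88.2% against 86.2%, adjusted permutation p = 1), GABA and glycine neurons, neural progenitors and radial glia, housekeeping genes, neuronal activity genes and the Hedgehog and Notch pathways. Of the lower lists, 10 kept their call and 6 lost it, namely microglia (adjusted permutation p = 0.634), myelinating oligodendrocytes (adjusted permutation p = 0.886), erythroid cells, lymphocytes, liver and heart. Midbrain regulators were lower only there (35.7% against 90.4%, adjusted permutation p = 0.000900). With the most 5' TSS of each gene, GABA and glycine neurons (adjusted exact p = 0.0897) and neuronal activity genes (adjusted exact p = 0.126) lost their call.

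**Figure D3:**
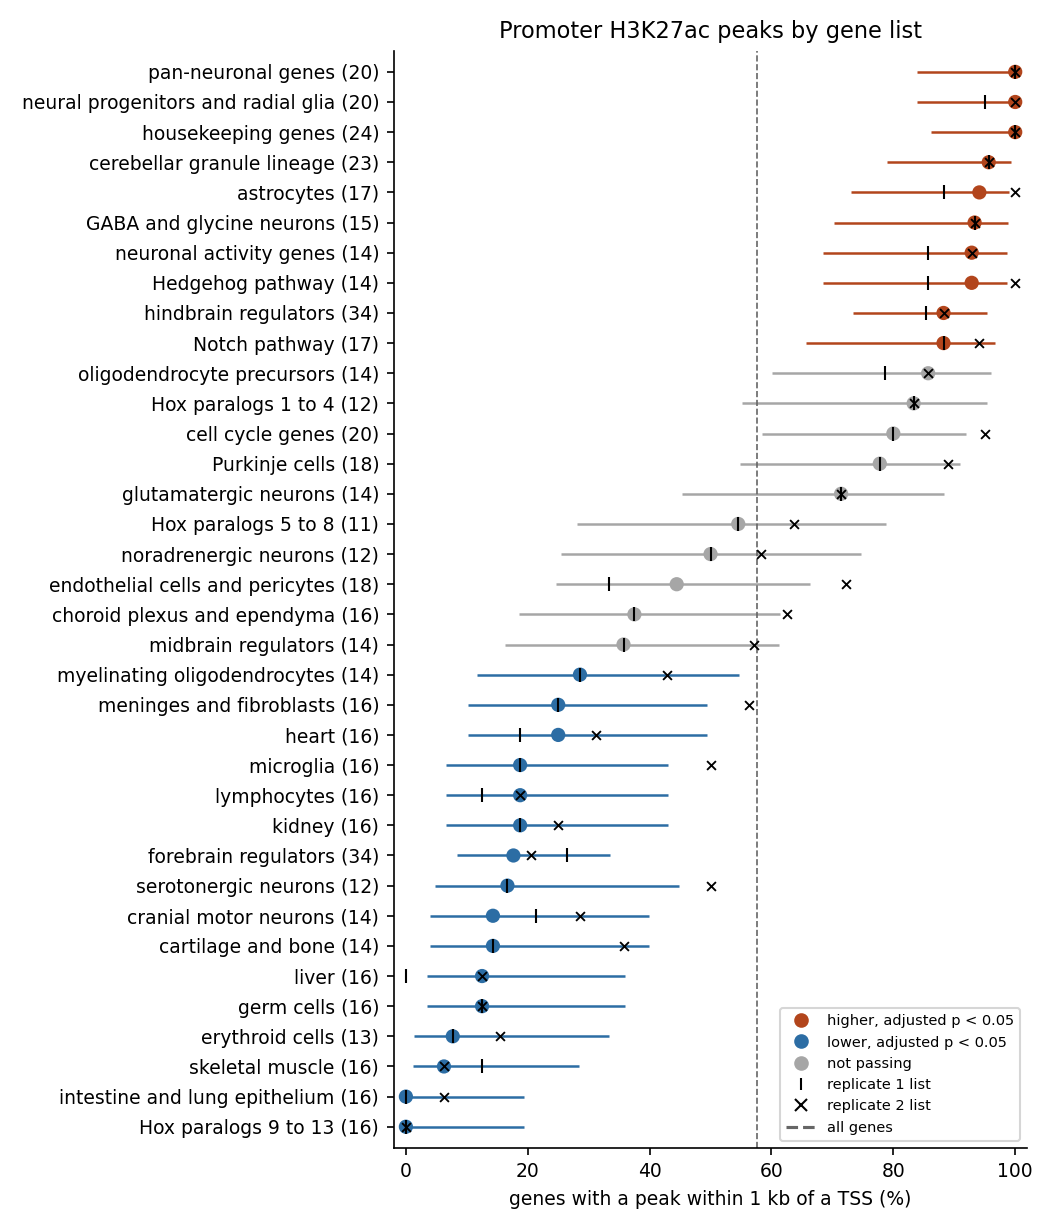
Share of genes with an H3K27ac peak within 1 kb of a TSS (x axis, percent) for each of the 36 gene lists (y axis, number of genes in brackets): dots give the replicated list with 95% Wilson intervals, bars and crosses the lists of replicates 1 and 2, and the dashed line all genes (57.6%). Red lists were higher and blue lists lower than other genes (10 and 16 lists), and grey lists did not pass.

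Distal peaks were most numerous around Msi2, Zmiz1 and Myt1l. The 35928 replicated peaks outside promoters had a median distance of 29.3 kb to the nearest protein-coding TSS, and 82.0% lay within 100 kb. The 10 genes with most distal peaks were Msi2, an RNA-binding regulator of progenitors (83 peaks; chromosome 11, 88339382 to 88718513), the transcriptional coregulator Zmiz1 (69; chromosome 14, 25459185 to 25666743), Myt1l (68; chromosome 12, 29528384 to 29923213), Gse1 (65; chromosome 8, 120228456 to 120581390) and the helix-loop-helix factor Tcf4 (60; chromosome 18, 69343356 to 69689079). They were followed by Ubash3b (59; chromosome 9, 41011098 to 41161697), Frmd4a (57; chromosome 2, 4017717 to 4614043), the neuronal splicing regulator Celf4 (54; chromosome 18, 25477632 to 25754157), Zfp423, needed for cerebellar vermis formation (52; chromosome 8, 87661810 to 87959595), and Zfp36l1 (52; chromosome 12, 80107754 to 80113013). Coordinates are mm10. The lists of the single replicates assigned 136 ± 21.2 peaks to Msi2, 116 ± 22.6 to Myt1l and 108.5 ± 12.02 to Zmiz1 (SD, n = 2), with Myt1l ahead of Zmiz1, and all 10 genes also had promoter peaks.

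The lists with most distal peaks per gene were the pan-neuronal genes, at 14.6 against 3.38 for random lists matched on territory length (4.32 times, adjusted permutation p = 0.00180), and neural progenitors and radial glia, at 13.4 against 3.39 (3.95 times, adjusted permutation p = 0.00180). The underlying p of 1e-04 is the smallest that 10000 random lists can give. Myt1l (68 peaks) and Celf4 (54 peaks, with a territory of 2552 kb) belong to the pan-neuronal list and raise its mean. The random lists were not matched on promoter peaks, which all genes of both lists and 57.5% of other genes had. The cerebellar granule lineage (7.65 peaks, 2.63 times, adjusted permutation p = 0.0126), astrocytes (7.47 peaks, 3.25 times, adjusted permutation p = 0.0126) and hindbrain regulators (5.62 peaks, 2.04 times, adjusted permutation p = 0.0468) also had more than matched genes. Forebrain regulators had 1.94 peaks per gene against 3.38 (adjusted permutation p = 1), and Hox paralogs 1 to 4 had 1.92 against 0.571 (adjusted permutation p = 0.0546). The latter passed in the list of replicate 1 (adjusted permutation p = 0.00180), in that of replicate 2 (0.0180), in the pooled list (0.0334) and with −log10 q of 5 or more (0.0438). In total 5 of the 36 lists passed (one-sided, Benjamini-Hochberg over the lists) and 10 before adjustment. With only peaks within 100 kb of the TSS, 3 lists passed, and the hindbrain regulators (adjusted permutation p = 0.0792) and the granule lineage (adjusted permutation p = 0.0630) did not. Hindbrain regulators also lost their call when distal peaks were counted from 2.5 kb of the TSS (adjusted permutation p = 0.0742).

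The widest acetylated regions lay over Hoxb genes, over Zic1 and Zic4 and over the miR-9 genes. Peaks within 1 kb of each other merged into 39183 regions of 1088 bp median width, and 100 regions exceeded 10 kb. The widest (47.5 kb; chromosome 11, 96308935 to 96356456) spanned the TSSs of Hoxb2, Hoxb3 and Hoxb4 and the Mir10a gene. The 3 annotated genes for miR-9, a microRNA that promotes neuronal differentiation, each lay in another of the 10: Mir9-1 (44.5 kb; chromosome 3, 88198160 to 88242653, nearest protein-coding TSS Rhbg at 34.3 kb), Mir9-3 (42.3 kb; chromosome 7, 79496275 to 79538589, nearest Polg at 51.1 kb) and Mir9-2 (33.6 kb; chromosome 13, 83712829 to 83746417, nearest Mef2c at 76.7 kb). The miR-9 genes were singled out after the regions were seen. The region of Zic1 and Zic4 measured 40.6 kb (chromosome 9, 91349827 to 91390459) and that of Nr2f2, an orphan nuclear receptor, 28.1 kb (chromosome 7, 70342838 to 70370901). A region over the non-coding gene Lncppara, nearest to Ppara at 58.0 kb, measured 27.5 kb (chromosome 15, 85663779 to 85691278). The regions at Pax6 (25.3 kb; chromosome 2, 105666527 to 105691860), Nfib (25.2 kb; chromosome 4, 82493158 to 82518342) and Notch1 (22.3 kb; chromosome 2, 26482400 to 26504716) completed the 10. Replicate 1 peaks covered 62.2% to 92.5% of these regions and replicate 2 peaks 82.7% to 96.8%.

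Of the 10 distal peaks of highest fold enrichment, all were intergenic with respect to protein-coding genes and 8 overlapped an annotated non-coding gene. Such an overlap was found for 20.5% of all 13171 intergenic distal peaks and for 36.7% of the 771 that were at least as wide as the narrowest of the 10, a comparison chosen after the peaks were seen. The highest (43.6 ± 12.9-fold; chromosome 7, 73615988 to 73619684) lay 76.4 kb from Chd2, a chromatin remodeller, and another near Chd2 (39.2 ± 6.29-fold; chromosome 7, 73556330 to 73559919) overlapped 1810026B05Rik (SD, n = 2). The peak nearest to Scyl1 (35.7 ± 4.67-fold; chromosome 19, 5799656 to 5807907) overlapped Malat1, an abundant nuclear RNA. The others were nearest to Spen (41.3 ± 16.6-fold; chromosome 4, 141544510 to 141548135), A830005F24Rik (39.3 ± 14.6-fold; chromosome 13, 48545293 to 48547414) and Mef2c (32.8 ± 1.35-fold; chromosome 13, 83713457 to 83734576, within the Mir9-2 region) (SD, n = 2). The last 4 were nearest to Wnt7b (38.0 ± 11.1-fold; chromosome 15, 85651822 to 85656633), Ppara (39.1 ± 11.7-fold; chromosome 15, 85666365 to 85674858), the calmodulin gene Calm1 (35.6 ± 12.6-fold; chromosome 12, 100185505 to 100189046) and Cplx2 (34.9 ± 8.63-fold; chromosome 13, 54301639 to 54304884) (SD, n = 2). Ranks follow the pooled fold. Of all distal peaks, 1417 (3.94%) lay within 1 kb of the start of a long non-coding gene. Distal was defined by protein-coding TSSs only, so some of the 10 may be promoters of non-coding genes.

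Several binding motifs were more frequent in distal H3K27ac windows than in background windows, with RFX the highest. The motif of RFX factors, regulators of ciliary genes, was found in 1.93% of 35704 windows of 500 bp against 0.625% of windows of matched GC content outside peaks (odds ratio 3.12, adjusted exact p = 8.73e-56). It was followed by MEF2 (odds ratio 2.37, adjusted exact p = 8.26e-23), the palindrome of nuclear factor I (odds ratio 1.87, adjusted exact p = 9.24e-28), the homeodomain core (odds ratio 1.55, adjusted exact p = 3.20e-61) and CTCF (odds ratio 1.55, adjusted exact p = 2.35e-05). The ZIC motif (23.3% against 17.2%, odds ratio 1.46), the POU octamer (odds ratio 1.45), the proneural E-box (60.9% against 53.6%, odds ratio 1.35), SOX (20.5% against 16.3%, odds ratio 1.32), HOX-PBX (odds ratio 1.24) and TEAD (odds ratio 1.07) were also more frequent. The GLI motif was less frequent (0.417% against 0.627%, odds ratio 0.665, adjusted exact p = 0.000212). The liver motifs HNF1 (1 peak window and 0 background windows) and HNF4 (odds ratio 1.08, adjusted exact p = 0.528), and GATA (0.934), CREB (1.17), ETS (1.14), NRF1 (1.00), EBF (1.10) and AP-1 (1.04) did not pass. The windows of the single replicates gave odds ratios of 2.84 ± 0.144 for RFX and 1.82 ± 0.00795 for nuclear factor I (SD, n = 2). AP-1 (adjusted exact p = 1.22e-07) and EBF (adjusted exact p = 0.00165) passed in the windows of replicate 2 alone, as they did in the pooled list (4.71e-07 and 0.000522), and EBF passed in windows of 300 bp (0.00967).

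In all, 11 of 20 motifs were more frequent and 1 less frequent by two-sided Fisher's exact tests over windows, which are not replicates. Background windows were matched on GC content alone. Other differences in sequence, such as repeat content, were not accounted for and may contribute to odds ratios near 1. Without matching on GC content, the log2 odds ratio turned negative for the homeodomain core (-0.82), HOX-PBX (-0.75) and the POU octamer (-0.39), GLI turned positive (0.36, adjusted exact p = 0.0609), and MEF2 (adjusted exact p = 0.509) and TEAD (adjusted exact p = 0.3999) no longer passed. AP-1 (adjusted exact p = 5.99e-08), ETS (2.90e-18), NRF1 (5.48e-05), EBF (2.81e-25) and CREB (2.07e-10) passed there instead, and GATA was less frequent (3.11e-32). In windows of 300 bp the log2 odds ratio of CTCF was -0.39 (adjusted exact p = 0.154).

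**Figure D4:**
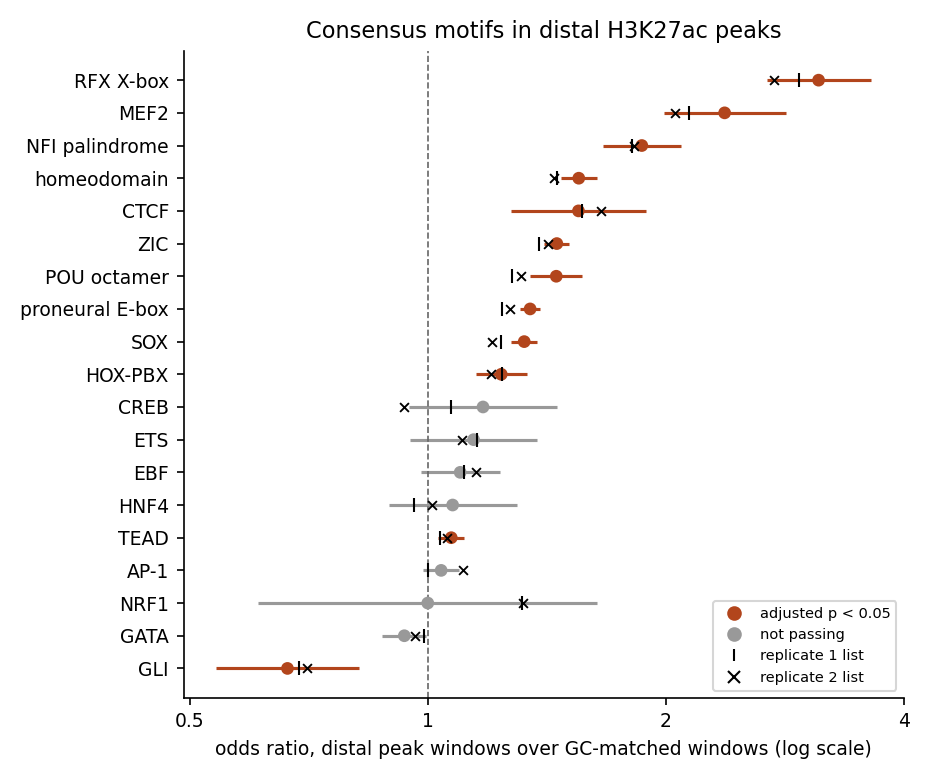
Odds ratio (x axis, log scale) of a consensus motif in 500 bp windows at distal peaks against GC-matched windows outside peaks, with 95% intervals, for the replicated list (dots) and for the lists of replicates 1 and 2 (bars and crosses). RFX was highest at 3.12 and GLI lowest at 0.665; HNF1 is not drawn, with 1 match in all.

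X-linked promoters were marked less often than autosomal ones. A promoter peak was found at 393 of 948 X-linked genes (41.5%) and at 12182 of 20722 autosomal genes (58.8%), a difference of -17.3 percentage points (two-sided Fisher's exact test, p = 1.34e-25). The difference was -18.1 points in the list of replicate 1 and -17.6 points in that of replicate 2. Autosomal lists matched on promoter CpG ratio had peaks at 46.3% of genes, which left a difference of -4.88 points. Chromosome X held 4.58 replicated peaks per Mb, against 14.5 on chromosome 3 and 34.5 on chromosome 11, the lowest and the highest of the autosomes. On chromosome Y, 4 replicated peaks were found, at the promoters of the broadly expressed genes Kdm5d, Uty and Ddx3y and 24.9 kb from the Kdm5d TSS.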

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

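The patterns were picked after the values of the comparisons were seen. The tests were planned before they were run, except the one with noradrenergic markers added to the sparse cells. The written predictions did not name the lists of sparse cells, and the first run of that test included noradrenergic markers. The choice of lists reported below was therefore not fixed in writing before a result was seen. The study has a single group, so no biological difference between groups was tested as an explanation. Outside the comparisons, 8 peaks of the replicated list lay on unplaced or unlocalised scaffolds, which no comparison used. No expected number was computed and no explanation was tested for these peaks.

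X-linked genes carried fewer promoter peaks than autosomal genes (41.5% against 58.8%). Lower CpG content, as matched by decile, did not account for the whole gap. Autosomal lists matched in this way had peaks at 46.3% of genes with a 95% range of 44.0 to 48.6. Matching lowered the difference to -4.88 percentage points. Differences in CpG ratio within a decile were not matched, so they may hold part or all of the rest. Multigene families and predicted genes, taken alone, do not account for the whole gap either: without them the difference was -12.9 percentage points (59.7% of 543 X-linked against 72.5% of 13917 autosomal genes, Fisher's exact test, p = 2.52e-10). Families were told by the stem of the gene symbol, so reads that map to several copies were not tested as such. That comparison was not matched on CpG ratio (median 0.353 on X and 0.519 on autosomes). Both explanations together were not tested, so the gap may come from the 2 combined. The median promoter fold of marked X-linked genes was 0.784 of the autosomal median (mean of 2 replicates, with 95% bootstrap intervals of 0.750 to 0.875 and 0.675 to 0.808), so the single X of the male animals in these mixed pools may contribute. Weaker enrichment at promoters of low CpG content could give the same ratio, and the control may be lowered alike, so this stays open. The sexes were pooled, so an effect on the X of the female animals could not be told apart from it and was not tested.

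Of the replicated list, 20.1% of peaks had no replicate 1 peak. A less sensitive replicate 1 list may account for this, since only 87 of the 12564 peaks in the top quartile of replicate 2 fold (0.692%) lacked one, against 14.5%, 35.3% and 30.4% in the quartiles below. The replicated list was itself derived from both single lists, so the low share in the top quartile may have been set by that selection. In the full replicate 2 list, 76.9% of top-quartile peaks were covered over at least 50% of their length by replicate 1 peaks. A different tissue makeup of the pools is not excluded, because peaks near 1 of 31 lists lacked a replicate 1 peak at another rate than peaks of like fold: neural progenitors and radial glia at 14.1% against 21.2% (adjusted permutation p = 0.0310). The overlap rule of the replicated list is not stated, and 114 of its peaks were in neither single list, so the way the list was made could also leave peaks without a replicate 1 peak. This was not tested, and all these explanations stay open.

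Markers of sparse cells (serotonergic and cranial motor neurons, microglia, endothelial cells and pericytes, myelinating oligodendrocytes) had replicated promoter peaks at 19 of 74 genes (25.7%). Low CpG content does not account for this over all 74 genes, because CpG-matched lists had peaks at 53.8% of genes, with a 95% range of 45.9 to 62.2. Of the single lists, serotonergic and cranial motor neurons were each below their matched lists (adjusted permutation p = 0.000900), while microglia (0.634), endothelial cells and pericytes (0.493) and myelinating oligodendrocytes (0.886) did not differ from theirs, so low CpG content stays open for these. Dilution of a few cells in whole tissue stays open. Of the 55 unmarked genes, 20 (36.4%) had a peak in another deposited list, against 8 of 119 unmarked genes of outside tissues (6.72%). The difference was 29.6 percentage points (Fisher's exact test, p = 2.50e-06), and 27.8 points with noradrenergic markers added. The rise in the replicate 2 list (serotonergic genes from 2 to 6, microglia from 3 to 8) was part of the comparisons seen before the pattern was picked. The outcome was thus largely known in advance, and the p-value is not independent evidence. Unmarked genes of sparse cells and of outside tissues were also not matched on CpG ratio. Weak acetylation in all cells would give the same values and was not tested.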

How the results depend on the processing

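The alternative that kept only replicated peaks with a peak in each replicate was chosen after the data were seen. The differences between hindbrain and forebrain regulators (58.8 to 75.6 percentage points), between Hox paralogs (50 to 83.3) and between X and autosomes (-18.1 to -16.9) kept their direction and call under the alternative peak lists, thresholds, windows and TSSs and, for the regulators, among genes of high CpG ratio. Matching on CpG ratio, tested apart, lowered the X difference to -4.88 points. The count of more frequent motifs stayed within 11 to 13, but without GC matching AP-1, ETS, NRF1, EBF and CREB took the place of the homeodomain core, HOX-PBX, the POU octamer, MEF2 and TEAD. Of the single-list and single-motif results, 431 of the comparisons with an alternative kept direction and side of the threshold, 32 lost a call, 25 gained one and 25 turned direction. For distal peaks these comparisons covered only the lists that passed, Hox paralogs 1 to 4 and forebrain regulators. Distal calls that other lists gained are not in these totals. Except where the construction of an alternative shows it, the cause was not tested.

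The share of replicate 1 peaks found in replicate 2 was 77.01% with 1 bp of overlap, 60.9% with 80%, 95.7% with −log10 q of 5 or more and 66.9% with lists of equal length. In the other direction these were 44.7%, 12.1%, 38.2% and 38.2%. Rho was 0.878 for −log10 p, 0.857 with −log10 q of 5 or more and 0.920 with 80% overlap. The promoter share of peaks was 20.2% to 27.5% leaving out either replicate, 18.1% in the pooled list and 35.5% with −log10 q of 5 or more. The share of genes was 56.5% to 60.7% leaving out either replicate and 61.3% in the pooled list. Lists differing in promoter share numbered 14 against CpG-matched lists, and lists with more distal peaks numbered 8 in the pooled list and 3 within 100 kb.

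Differences in promoter share that turned direction were, in percentage points, -4.77 for Hox paralogs 1 to 4 with the most 5' TSS, 4.64 for Hox paralogs 5 to 8 with 2.5 kb windows, and against CpG-matched lists -4.03 for Purkinje cells, -5.45 for glutamatergic neurons and -7.89 for cell cycle genes. Leaving out either replicate gave -1.95 to 2.97 for Hox paralogs 5 to 8, -23.2 to 11.6 for endothelial cells and pericytes and -19.01 to 1.83 for choroid plexus and ependyma, each positive without replicate 1. In the pooled list they were 2.37, 5.40 and 7.49 for those lists, and 7.49 for meninges and fibroblasts, the only one of these with a call in the main comparison.

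Log2 odds ratios that turned direction without GC matching were -0.82 (homeodomain), -0.75 (HOX-PBX), -0.39 (POU octamer), 0.36 (GLI) and -0.031 (HNF4). In 300 bp windows they were -0.39 (CTCF), -1.58 (HNF1), -0.031 (HNF4) and -0.40 (CREB). HNF4 gave -0.060 to 0.018 leaving out either replicate and -0.065 with −log10 q of 5 or more, and CREB gave -0.10 to 0.097 and, in the pooled list, -0.085. Depth is unknown, and the number of peaks per list limits what weak promoters can show.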

Other observations

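The test of 6 lists was planned, and the reading of all other lists was chosen after the result was seen.

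A shift in promoter fold between the replicates was looked for as a sign that the pools held different parts of the hindbrain. Over 12127 genes the replicate 2 fold exceeded that of replicate 1 by a median of 0.62 on the log2 scale, a scale the separate calls do not share. Of the planned lists with 5 or more genes measured, hindbrain regulators, Hox paralogs 1 to 4, the cerebellar granule lineage and choroid plexus and ependyma, none lay outside the central 95% of random lists of like fold, and the farthest, Hox paralogs 1 to 4, lay at percentile 5.66. This leaves a different makeup of the pools open, because only genes with a peak in both replicates have a ratio, and 11 of the 69 genes of the planned lists with a peak had it in a single replicate. Meninges and fibroblasts and erythroid cells had too few genes with a fold in both replicates. Of all 21 lists measured, 1 lay outside that range: neuronal activity genes, at percentile 99.4, with 9 of 12 genes above the median of all genes. Several lists lay low without passing that bound: 9 of the 21 were below percentile 10, with the Hedgehog pathway (3.28), pan-neuronal genes (4.27) and Hox paralogs 5 to 8 (4.31) the lowest, and 2 were above percentile 90. The lists share genes, and this crowding was not tested.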
